A study of Mus musculus with 15 samples.

How the data were processed

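RNA sequencing was done on 15 libraries of microglia derived from mouse embryonic stem cells, 6 untreated and 3 for each of the LPS+IFNg, IL4 and TGFb stimuli. Per the labels' protocols, total RNA was extracted with TRIZOL and made into libraries with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the reads were processed with TopHat2 2.0.3, Partek 6.6, R 3.0.2 and DESeq2, with the mouse build mm10. The gene annotation, the rule for counting reads and the use of strand were not given in the sources used here, so overlapping and antisense genes and near-identical copies cannot be told apart by strand or by unique reads.

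The deposited table holds a normalized signal per gene and library, in which the authors divided read counts by 1 factor per library and set every value below 1 to exactly 1. Both steps were inferred from the values. Dividing by the value of 1 read gave whole numbers for 100% of the values above 1 in every library, within a tolerance of 0.01 reads. Of the 11201 genes, 276 had at least 1 value at the floor of 1, which stands for at most 2 reads in the deepest library, at most 1 in 6 others and 0 in the remaining 8. The lowest of the genes' highest values was 11.1, so the table used here holds no gene that was low in every library, and a gene absent from it was not analysed here. The recovered reads summed to 2682564 to 18676181 per library. All 15 value columns were used, and 0 columns were left out.

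Groups were taken from the stimulation given in the labels. Replicate numbers were given in accession order and only name the libraries. A chi-square test of recovered reads, which takes reads as independent and covers counting noise only, was used to look for a library deposited more than once and found no such pair. It does not show that the libraries are separate biological replicates.

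Because the values are normalized, the main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with the empirical Bayes trend, 1 fit over all 15 libraries and the 6 contrasts between groups. Genes with a value of at least 10 in at least 3 libraries were tested, 11138 of 11201. Calls were made at a Benjamini-Hochberg adjusted p below 0.05 within a contrast, and a size filter of 1 on the log2 scale was counted beside them. A fold change on this scale understates the change of genes with low values. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, for the 27 of 36 fixed lists that had at least 5 tested members, with adjustment over lists within a comparison. List members were matched by symbol.

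The tests, the gene lists, the marker panels and the rule for naming genes were fixed before the data were examined. For each stimulus against untreated the rule took the measured members of its marker panel, the 6 highest and 6 lowest called genes with a mean of at least 50 in the higher group and no overlap between the libraries of the groups, and up to 4 called members, by moderated statistic, of each list that camera called or that had at least 3 called members. Between stimuli it took the 5 highest and 5 lowest. Predicted genes, RIKEN clones, ribosomal protein genes and microRNA genes were left out of the ranked part. Some genes that the rule took are not reported here. Members of the lists of other cell types are named in addition to the rule.

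For a gene with 0 recovered reads in a group, the fold is a lower bound with that group set at 3 counts over the whole group. With 1 to 3 reads, the ratio of reads, each divided by the total of its group, is given as a depth-adjusted ratio with its 95% exact Poisson interval. Values at the floor were taken as 0 reads, and each ratio is also given with the group of fewer reads at the most reads its floored values allow. A gene at or under 3 reads in both groups was given no fold and was left out of list medians at the bound. Such bounds and intervals cover counting error only, as reads without molecular identifiers are not independent molecules. Gene positions came from GENCODE M21 (GRCm38, the build the submitters name as mm10), in which 95.4% of the symbols had 1 position. GC content and length of the longest transcript were found for 95.5% of the symbols.

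The scripts were tested on simulated reads drawn from the real means, depths and dispersions, with 200 genes changed by known folds and the same floor. For LPS+IFNg against untreated, limma recovered 26% of 50 genes changed 1.25-fold, 76% at 1.5-fold, 92% at 2-fold and 94% at 4-fold among 11138 genes. For IL4 these shares were 42%, 70%, 94% and 96%, and for TGFb 26%, 66%, 82% and 94%. False calls among the 10938 unchanged genes numbered 5, 6 and 7. In the real comparisons limma called 6562, 1917 and 5290 genes, far more than the 200 changed here. The adjustment is stricter when few genes change, so these shares do not measure the sensitivity in the real data. The known size factors were used, so error in scaling was not covered. A list of 20 genes raised 1.5-fold was called in each simulation and 0 of 26 random lists were. The simulated genes were drawn independently, so the list result does not cover lists whose members vary together between libraries.

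The alternatives fixed beforehand were other pseudocounts (0.1 and 10), filters, scalings, variance models, a stricter threshold, fits of the compared groups alone and fits without each library. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, a fit without the 3 libraries with the fewest reads, and a fit with floored values at the highest number of reads they allow. Overlaps between stimuli were set beside 20 simulations of unchanged groups and beside 10 divisions of the untreated libraries into 3 and 3, each used both ways.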

Results

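The series measured messenger RNA in cultured microglia derived from mouse embryonic stem cells, a laboratory model of the immune cells of the brain. Cells were left untreated (6 libraries) or were stimulated for 24 h, with 3 libraries for each stimulus. The stimuli were a mixture of lipopolysaccharide (LPS, a bacterial cell wall component, 500 ng/ml) and interferon gamma (IFNg, 20 ng/ml), interleukin 4 (IL4, 100 U/ml) and transforming growth factor beta (TGFb, 50 ng/ml). The deposited table held normalized read counts for 11201 genes in 15 libraries. Whole reads could be recovered from it, and they summed to between 2682564 and 18676181 reads per library, with a median of 7589049. The untreated libraries held 2682564 to 18676181 reads, the LPS+IFNg libraries 7589049 to 10170627, the IL4 libraries 5523959 to 14361911 and the TGFb libraries 3715535 to 13403411. Values below are means ± SD of normalized read counts with n = 6 untreated and n = 3 libraries per stimulus. Fold changes are on the log2(value + 1) scale with their standard error (SE), values written as N-fold are ratios of group means unless given as a bound, and adjusted p-values come from limma with Benjamini-Hochberg adjustment. Positions are those of GENCODE M21 on GRCm38 (mm10), and each positioned gene was annotated as protein coding. Nothing in the labels says whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

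The 4 groups separated on the leading principal components of the log2 values. The first component held 61.7% of the variance and set the 3 LPS+IFNg libraries (74 to 91.1) apart from the other 12 libraries, all of which lay below 0. The second component held 17.6% and set apart the TGFb libraries (-42.7 to -39.6), and the third held 5.1% and had its lowest values in the IL4 libraries (-23.9 to -16.6). Within the LPS+IFNg group, replicate 3 stood apart from the others. The chi-square of its recovered reads per degree of freedom was 26.36 against replicate 1 and 27.01 against replicate 2, where replicates 1 and 2 gave 2.9. Pairs of untreated libraries gave 1.42 to 2.94, pairs of TGFb libraries 1.59 to 2.17 and pairs of IL4 libraries 2.61 to 7.63. The chi-square covers counting noise only and grows with depth. The IL4 pair at 7.63 was replicates 1 and 3, with 12986954 and 14361911 reads. Its root mean square log2 difference, which low depth raises, was 0.278, where untreated pairs gave 0.225 to 0.412. By that measure LPS+IFNg replicate 3 gave 0.465 and 0.488, and replicates 1 and 2 gave 0.248.

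**Figure D1:**
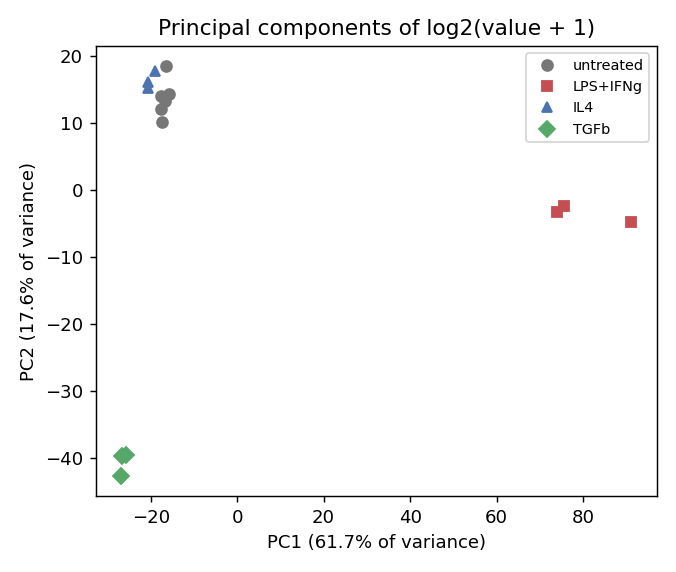
Each point is 1 library on the first and second principal components of log2(value + 1) over the 11138 genes tested, with the percent of variance on each axis; the symbol gives the group. The LPS+IFNg libraries lie at 74 to 91.1 on the first component and the TGFb libraries at -42.7 to -39.6 on the second.

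Stimulation with LPS+IFNg was compared with no treatment to find the genes of a classically activated state. The largest increases included interferon-inducible GTPases and serine protease inhibitors. Gbp5 (chromosome 3, 142493978 to 142522344), a guanylate-binding protein, rose from 1.82 ± 1.2 to 7715 ± 3580, a log2 fold change of 11.42 (SE 0.34), and Gbp2 (chromosome 3, 142620602 to 142638008) rose from 14.2 ± 6.1 to 43190 ± 29000. Nos2 (chromosome 11, 78920787 to 78960254), which encodes inducible nitric oxide synthase, rose from 4.78 ± 3.36 to 5730 ± 3980 with an adjusted p of 2.49e-12. The interferon-gamma-induced chemokine gene Cxcl10 rose from 12.7 ± 3.43 to 7997 ± 7730, and the transcription factor gene Irf1 rose from 77.2 ± 7.97 to 7739 ± 1890. Without replicate 3 of the LPS+IFNg group the mean of Gbp2 was 26450, that of Nos2 3435 and that of Cxcl10 3536. Among genes with a mean of at least 50 in the higher group, the deepest decreases were in Atp2b4 (chromosome 1, 133699457 to 133801041), a plasma membrane calcium pump gene, which fell from 149 ± 10.8 to 6.98 ± 4.15, in Ankrd37, which was 22.6-fold lower, and in Cytip, an adhesion regulator, which was 17.4-fold lower.

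In all, limma called 6562 of 11138 genes, 3284 higher and 3278 lower, and 1189 of them differed at least 2-fold (787 higher, 402 lower). The balance of directions depended on the scaling. Rescaling each library to the same total moved the median of all genes by -0.12 on the log2 scale and left 35.5% of the calls higher in place of 50%, and quantile normalization left 38.8% higher.

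The other genes among the highest were Serpina3f (2.12 ± 1.88 to 6805 ± 4450) and Serpina3g (4.37 ± 4.09 to 7270 ± 4210), which encode serine protease inhibitors, Iigp1 (4.26 ± 3.23 to 7674 ± 3860) and Gbp6. In the other direction they were Hspb7 (15.7-fold lower), Abca9 (12.8-fold lower) and Rgs2 (1186 ± 78.6 to 102 ± 19). Without replicate 3 the means with LPS+IFNg were 4237 for Serpina3f and 4838 for Serpina3g, and without untreated replicate 1 the untreated mean of Serpina3f was 1.41. Gbp6 had 0 recovered reads in untreated cells and 6908 with LPS+IFNg, which made it at least 3770-fold higher after adjustment for depth when the untreated group is set at 3 counts. With the 2 untreated reads that the floor allows at most, the depth-adjusted ratio was 5660 (95% counting interval 1570 to 46700). The guanylate-binding proteins, Serpina3f with Serpina3g, and the class I histocompatibility genes have near-identical relatives, so the division of reads within each family is uncertain.

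Of the marker panel fixed for this state, Tnf rose from 176 ± 12 to 3743 ± 1140, Ccl5 from 8.52 ± 4.4 to 4190 ± 1590, Cd40 from 68.95 ± 4.6 to 1273 ± 817 and Il1b from 6.48 ± 3.16 to 18.5 ± 2.6. Without replicate 3 the mean of Cd40 with LPS+IFNg was 801.6. Cd86 stood at 99.8 ± 54.8 against 70.4 ± 9.76 in untreated cells (adjusted p = 0.143 with limma). Without replicate 1 of the LPS+IFNg group its log2 fold change was 0.66 and it passed the test. Il6 and Il12b were not analysed here.

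Every tested member rose in 4 of the fixed lists. All 32 tested interferon-stimulated antiviral genes rose, with a median log2 fold change of 4.92 (5.22 with genes at 0 reads in a group set at their bound). Among them were the ADP-ribosyltransferase gene Parp14 (50.2 ± 8.61 to 4735 ± 163) and Oasl1 (147 ± 10.2 to 3426 ± 602). All 16 interferon-inducible GTPases rose, with a median of 8.24 (9.35 with such genes at their bound), including Irgm1 (133 ± 21.7 to 3019 ± 230). All 19 genes of class I antigen presentation rose (median 2.45), for example the peptide transporter gene Tap1 (309 ± 23.9 to 6186 ± 1320), Tapbp (1031 ± 41.9 to 9756 ± 531) and H2-K1 (2343 ± 67.9 to 12850 ± 553). All 20 genes of the NF-kB pathway and its feedback rose (median 2.15), among them the inhibitor genes Nfkbia (305 ± 24.2 to 4062 ± 799) and Tnfaip3 (288 ± 20.9 to 2484 ± 680). The camera tests of these 4 lists gave adjusted p-values of 3.62e-26, 3.54e-16, 1.17e-18 and 5.08e-15, in that order.

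Of 11 chemokine genes 10 rose and 1 fell, and of 14 inflammatory cytokine and enzyme genes 12 rose and 0 fell. Ccl3 rose from 481 ± 35.6 to 4032 ± 656 and Ccl4 from 80.6 ± 10.5 to 1841 ± 1070 (1225 without replicate 3). Of 18 genes of the NADPH oxidase and of NRF2 targets, 13 rose and 3 fell. Cybb, the catalytic subunit of the phagocyte oxidase, went from 4329 ± 257 to 32450 ± 1660 and the cystine transporter gene Slc7a11 from 1147 ± 73 to 4184 ± 644. Genes of class II antigen presentation (5 of 6 higher and 0 lower, camera adjusted p = 0.00175) included the class II transactivator Ciita, which had 1 recovered read in untreated cells and 296 with LPS+IFNg, a depth-adjusted ratio of 485 (95% counting interval 86.3 to 19200). With the 3 untreated reads that the floor allows at most, the ratio was 162 (54.8 to 788). The mean of Ciita with LPS+IFNg was 101, and 39.4 without replicate 3. That list had an adjusted p = 0.196 with an estimated correlation. Of 12 co-stimulatory and checkpoint ligand genes 9 rose and 2 fell, with Cd274 (PD-L1) going from 91 ± 11.3 to 2498 ± 1670 (1536 without replicate 3), and the camera adjusted p of 0.000954 became an adjusted p = 0.175 with an estimated correlation. Of 27 pattern recognition genes 13 rose and 7 fell, with Clec4e going from 59.9 ± 10.3 to 6055 ± 1620 and Nlrp3 from 195 ± 19.2 to 1161 ± 248 (adjusted p = 0.165 with an estimated correlation). Of 20 complement and phagocytic receptor genes 11 rose and 4 fell, among them complement C3 (1280 ± 66.7 to 24880 ± 7350) and the scavenger receptor gene Marco (9.95 ± 2.67 to 557 ± 35). The camera adjusted p of that list was 0.0419 (adjusted p = 0.478 with an estimated correlation), and it was 0.182 without replicate 3 of the LPS+IFNg group, 0.0509 with a minimum value of 50 and 0.0527 without the 3 libraries with the fewest reads.

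Genes of lipid handling and of the resting microglial state fell. Of 19 LXR targets and lipid handling genes 18 fell and 0 rose (median -0.63, camera adjusted p = 8.63e-08). Apoe, the main lipid carrier of the brain, went from 15730 ± 1250 to 4501 ± 534 and Scd2 from 42160 ± 1920 to 16480 ± 866. Of 19 homeostatic microglia genes 10 fell and 1 rose (camera adjusted p = 0.00277), including the transcription factor gene Mef2c (436 ± 42.1 to 142 ± 12.3). Of 19 disease-associated microglia genes 12 fell and 2 rose, with Igf1 going from 1615 ± 78.5 to 337 ± 57.5 and Cst7, one of the 2, from 422 ± 20.7 to 2728 ± 375 (adjusted p = 0.131 with an estimated correlation). Of 23 cholesterol synthesis genes 13 fell and 2 rose, for example Sqle (1204 ± 58.7 to 622 ± 41.7), with an adjusted p = 0.0821 with an estimated correlation. Of 22 alternative activation genes 5 rose and 5 fell, and camera did not call the list (adjusted p = 0.402). The mannose receptor gene Mrc1, one of its members, fell from 4830 ± 257 to 1230 ± 64.9. The counts adjusted over the list alone were the same for each list named in these paragraphs.

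Camera called 18 of 27 lists for LPS+IFNg, 10 of which held with an estimated correlation. Without replicate 3 of the LPS+IFNg group the log2 fold change of Cxcl10 was 8.06 in place of 8.81, that of Ciita 4.32 in place of 5.15 and that of the complement gene C1qb 6.35 in place of 7.06.

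**Figure D2:**
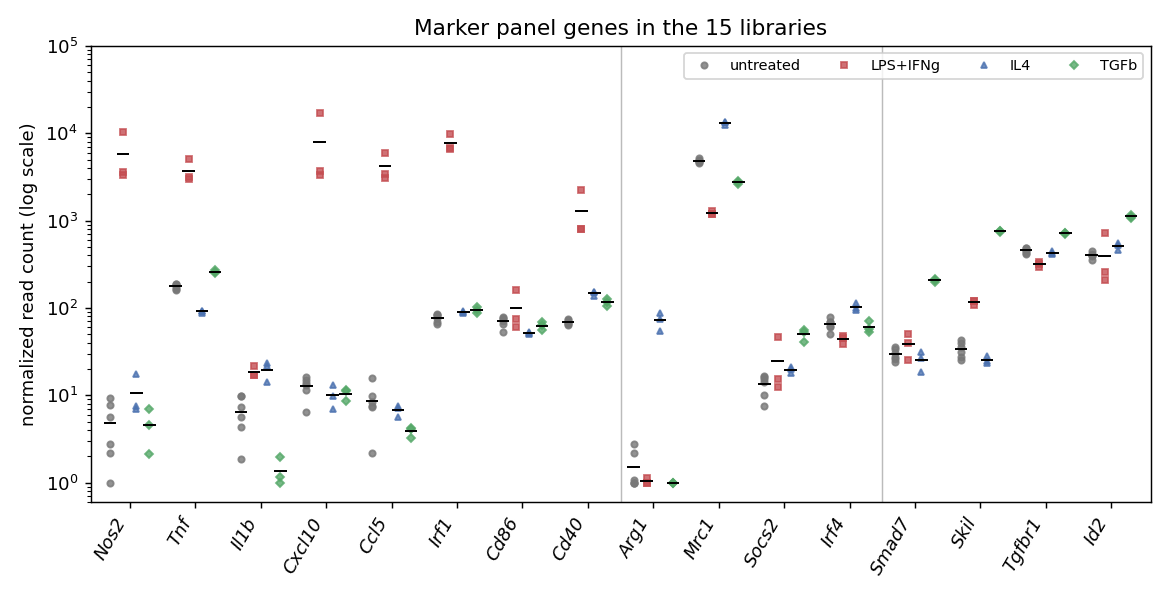
Normalized read counts on a log scale for 16 measured genes of the 3 marker panels, in panel order with vertical lines between panels. Each point is 1 library, the symbol gives the group and the black bar its mean; Nos2, for example, stands at 5730 with LPS+IFNg (3435 without replicate 3) and 4.78 in untreated cells.

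Stimulation with IL4 was compared with no treatment to find the genes of an alternatively activated state. Arg1 (chromosome 10, 24915221 to 24927484), the arginase gene that marks this state, rose from 1.51 ± 0.79 to 72.2 ± 17, a log2 fold change of 4.89 (SE 0.33) with an adjusted p of 6.6e-09. The mannose receptor gene Mrc1 rose from 4830 ± 257 to 13040 ± 644. Tlr8 (chromosome X, 167242696 to 167264329), a sensor of single-stranded RNA, rose from 4.6 ± 1.74 to 79.7 ± 7.37, and Cish, a STAT5-induced feedback inhibitor of cytokine signalling, rose from 8.3 ± 4.95 to 88.6 ± 1.22. The invariant chain gene Cd74 rose from 224 ± 22.7 to 1525 ± 8.4. The deepest decrease among genes with a mean of at least 50 in the higher group was that of the stress kinase gene Map3k5 (95.5 ± 6.52 to 30.7 ± 8.24).

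In all, limma called 1917 genes, 1101 higher and 816 lower, of which 114 differed at least 2-fold (85 higher, 29 lower). Rescaling to the same total left 34% of the calls higher in place of 57.4%. Without replicate 2 of the IL4 group, 1139 genes were called.

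Also among the highest were Lipn, a lipase gene (39 ± 8.93 to 356 ± 26.9), and Azin2 (7.7 ± 2.5 to 61 ± 9.06). Among the lowest were Hivep2 (2.53-fold lower), haptoglobin Hp (349 ± 23.6 to 151 ± 16.5), Arhgap24 (2.26-fold lower) and Pid1 (2.13-fold lower). Hp no longer passed the limma test without replicate 2 of the IL4 group (log2 fold change -1.12, adjusted p = 0.0598) or without the 3 libraries with the fewest reads (-1.16, adjusted p = 0.0553). In the panel fixed for this state, Irf4 rose from 65.2 ± 9.63 to 103 ± 10.5 and Socs2 stood at 19.5 ± 1.59 against 13.4 ± 3.71 (adjusted p = 0.275 with limma). Retnla, Chil3, Ccl17 and Ccl22 were not analysed here.

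Of 22 alternative activation genes 14 rose and 0 fell (16 rose and 0 fell adjusted over the list alone), with a median log2 fold change of 0.91 and a camera adjusted p of 5.66e-12. Besides Arg1 and Mrc1 they included the lectin gene Clec10a (150 ± 5.45 to 398 ± 32.9) and the VEGF receptor gene Flt1 (3599 ± 203 to 5973 ± 184). Of 35 cell cycle genes 28 fell and 0 rose (29 adjusted over the list alone; camera adjusted p = 3.58e-18). The change was small, with a median of -0.28, for example Mki67 (3956 ± 88.8 to 2859 ± 414), Top2a (3550 ± 114 to 2759 ± 75.1) and the spindle gene Tpx2 (1999 ± 31.8 to 1489 ± 25.8). Of 29 genes of the TCA cycle and respiratory chain 21 rose and 0 fell (25 adjusted over the list alone; median 0.2, camera adjusted p = 3.03e-13). They included the succinate dehydrogenase genes Sdhb (1099 ± 34.8 to 1438 ± 90.5) and Sdha (4797 ± 178 to 5767 ± 38.9).

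Of 23 lysosome genes 13 rose and 0 fell (14 adjusted over the list alone), with Psap going from 26110 ± 909 to 36070 ± 225 (camera adjusted p = 5.8e-07, adjusted p = 0.347 with an estimated correlation). Of 19 disease-associated microglia genes 11 rose and 1 fell (14 and 2 adjusted over the list alone), among them Igf1 (1615 ± 78.5 to 2928 ± 137) and the galectin gene Lgals3 (18360 ± 863 to 29350 ± 1500), with an adjusted p = 0.0606 with an estimated correlation. Of 20 complement and phagocytic receptor genes 6 rose and 1 fell (7 and 2 adjusted over the list alone), led by C3 (1280 ± 66.7 to 4861 ± 361), with an adjusted p = 0.473 with an estimated correlation. Of 19 LXR targets 7 rose and 0 fell (8 and 1 adjusted over the list alone), among them the cholesterol exporter gene Abcg1 (2362 ± 77.8 to 3583 ± 70.5). That call was lost with an estimated correlation (adjusted p = 0.0606) and under quantile normalization (adjusted p = 0.081). Of 18 oxidase and NRF2 target genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with Cybb going from 4329 ± 257 to 2483 ± 149 (adjusted p = 0.17 with an estimated correlation). Camera called 10 of 27 lists for IL4, and 3 of them held with an estimated correlation, those of alternative activation, the cell cycle and the TCA cycle.

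Of 14 inflammatory cytokine and enzyme genes 3 rose and 2 fell with IL4, the same adjusted over the list alone, and of 11 chemokine genes 2 rose and 2 fell (3 and 3 adjusted over the list alone). Camera called neither list (adjusted p = 0.968 and 0.514). Tnf fell from 176 ± 12 to 91.6 ± 2.81, the chemokine gene Ccl3 from 481 ± 35.6 to 230 ± 15.2 and Tlr2 from 523 ± 37.2 to 264 ± 38.5. Meanwhile Ccl2 rose from 55.1 ± 12 to 137 ± 19.5, Ccl7 from 2.4 ± 1.71 to 20.2 ± 0.623 and the cannabinoid receptor gene Cnr2 from 3.64 ± 2.05 to 14.2 ± 1.31. The chaperone gene Pdia4 rose from 1022 ± 36.1 to 2308 ± 53.5. For the 6 class II antigen presentation genes, which include Cd74, the median log2 fold change was -0.05 (-0.08 without Ciita, which had 1 recovered read in untreated cells and 0 with IL4) and the mean 0.5, and camera did not call the list.

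Stimulation with TGFb was compared with no treatment to find the response to a factor that microglia depend on in the brain. Among the highest were Olfml3 (chromosome 3, 103722222 to 103738001), a secreted protein gene typical of microglia, the kinase gene Sgk1 (2.96 ± 2.16 to 135 ± 19.3), the fatty acid hydroxylase gene Cyp4f18 (6.8 ± 1.4 to 262 ± 19.3) and the integrin gene Itgb5 (21.4 ± 6.66 to 562 ± 10.2). Olfml3 had 1 recovered read in untreated cells and 867 with TGFb, a depth-adjusted ratio of 1310 (95% counting interval 235 to 52000). The floor may hide reads, and with the 3 untreated reads it allows at most the ratio was 438 (149 to 2130). The pathway feedback genes Skil and Smad7 both rose, with Skil (chromosome 3, 31095058 to 31122577) going from 33.8 ± 7.03 to 759 ± 12.1, a log2 fold change of 4.47 (SE 0.15; adjusted p = 7.69e-14), and Smad7 from 29.5 ± 4.53 to 207 ± 7.75. The deepest decrease was in Gas7 (chromosome 11, 67455437 to 67688990), an actin-associated protein gene, which fell from 1164 ± 35.9 to 8.01 ± 3.45, a log2 fold change of -7.1 (SE 0.16). The next lowest among all genes tested was the properdin gene Cfp, at -3.44 (560.5 ± 36.7 to 51 ± 6.03).

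In all, limma called 5290 genes, 2686 higher and 2604 lower, of which 563 differed at least 2-fold (415 higher, 148 lower). Rescaling to the same total left 37.8% of the calls higher in place of 50.8%.

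Among the lowest were the chemokine gene Ccl9 (130 ± 7.53 to 22.1 ± 5.43), Lrrc25 (5.66-fold lower), Aoah, an enzyme that inactivates LPS (5.41-fold lower), and the phosphatase gene Ptpn22 (242 ± 27.2 to 54.3 ± 8.61). Of the panel fixed for this stimulus, the receptor gene Tgfbr1 rose from 455 ± 32.7 to 720 ± 9.82 and Id2 from 403 ± 29.9 to 1115 ± 51. Tgfbi, Pmepa1 and P2ry12 were not analysed here.

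Of 22 TGF-beta pathway targets 18 rose and 1 fell, with a median log2 fold change of 0.96 and a camera adjusted p of 4.41e-08, among them the repressor gene Ski (513 ± 66.1 to 1557 ± 20.5). Of 19 homeostatic microglia genes 14 rose and 0 fell (median 0.77, camera adjusted p = 4.69e-08), such as Golm1 (549 ± 31.7 to 1020 ± 5.82) and Selplg (357 ± 21.7 to 681 ± 1.83). Of 35 cell cycle genes 31 fell and 0 rose (median -0.53, camera adjusted p = 8.13e-16). Examples were the mitotic kinase gene Aurka (747 ± 21.8 to 352 ± 4.74), Kif20a (1046 ± 37.2 to 527 ± 65) and cyclin B1, Ccnb1 (1175 ± 88.5 to 710 ± 15.4). These 3 lists were the ones that held with an estimated correlation, of 14 of 27 called by camera.

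Of 23 lysosome genes 18 rose and 2 fell, with the protease gene Ctsd going from 31490 ± 1070 to 97380 ± 2630 (camera adjusted p = 6e-06, adjusted p = 0.299 with an estimated correlation). Of 19 LXR targets 11 rose and 6 fell (11 and 7 adjusted over the list alone), with Apoe going from 15730 ± 1250 to 59320 ± 2210 and Srebf1 from 2547 ± 217 to 6672 ± 55.6. That call was lost with an estimated correlation (adjusted p = 0.167), with a minimum value of 50 (adjusted p = 0.066), under quantile normalization (adjusted p = 0.214) and without replicate 3 of the LPS+IFNg group, whose libraries share the estimate of spread (adjusted p = 0.0655). Of 19 disease-associated microglia genes 11 rose and 4 fell, among them Trem2 (1693 ± 55.1 to 2822 ± 200) and Cd9 (4123 ± 133 to 8020 ± 413), with an adjusted p = 0.299 with an estimated correlation and an adjusted p = 0.0565 under quantile normalization. Of 15 immediate early and heat shock genes 8 rose and 0 fell, among them Fos (112 ± 10.3 to 485 ± 21) and Egr2 (42.4 ± 9.37 to 170 ± 6.24), with an adjusted p = 0.168 with an estimated correlation and an adjusted p = 0.0551 with a minimum value of 50. Of 12 co-stimulatory and checkpoint genes 8 rose and 0 fell (9 adjusted over the list alone), including Havcr2 (215 ± 29.6 to 484 ± 31.6), with an adjusted p = 0.299 with an estimated correlation.

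Of 29 genes of the TCA cycle and respiratory chain 22 fell and 0 rose (median -0.23), with cytochrome c, Cycs, going from 1445 ± 72 to 756 ± 24.8 (camera adjusted p = 2.39e-07, adjusted p = 0.126 with an estimated correlation). Of 23 cholesterol synthesis genes 12 fell and 1 rose, for example Idi1 (345 ± 11.2 to 165 ± 16.5), with an adjusted p = 0.0969 with an estimated correlation. Of 18 oxidase and NRF2 target genes 13 fell and 3 rose, with Cybb going from 4329 ± 257 to 1291 ± 34.9 and Slc7a11 from 1147 ± 73 to 328.5 ± 17.8 (adjusted p = 0.126 with an estimated correlation). In the list of the unfolded protein and amino acid stress response 9 genes fell and 7 rose (9 and 8 adjusted over the list alone). Those that fell included the biosynthetic enzyme genes Psat1 (3313 ± 149 to 1185 ± 29.3), Shmt2 (1638 ± 42.3 to 709 ± 13.7), Asns (744 ± 42.4 to 204 ± 24.3) and Mthfd2 (935 ± 35.2 to 252 ± 33.1). The list's camera adjusted p was 0.0466 (adjusted p = 0.168 with an estimated correlation). The camera call was also lost without replicate 4 of the untreated group (adjusted p = 0.0645) and without replicate 1, 2 or 3 of the LPS+IFNg group (adjusted p = 0.0536, 0.0518 and 0.0807). It was lost as well under total scaling (adjusted p = 0.109), under quantile normalization (adjusted p = 0.0897), with a minimum value of 50 (adjusted p = 0.066) and without the 3 libraries with the fewest reads (adjusted p = 0.0658). Of 11 chemokine genes 5 fell and 1 rose, the last being Cxcl16 (11 ± 5.41 to 53.7 ± 6.57), with an adjusted p = 0.299 with an estimated correlation. That camera call was also lost under total scaling (adjusted p = 0.073) and without replicate 4 of the untreated group (adjusted p = 0.0537). Except where given, the counts adjusted over the list alone were the same as those over all genes.

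**Figure D3:**
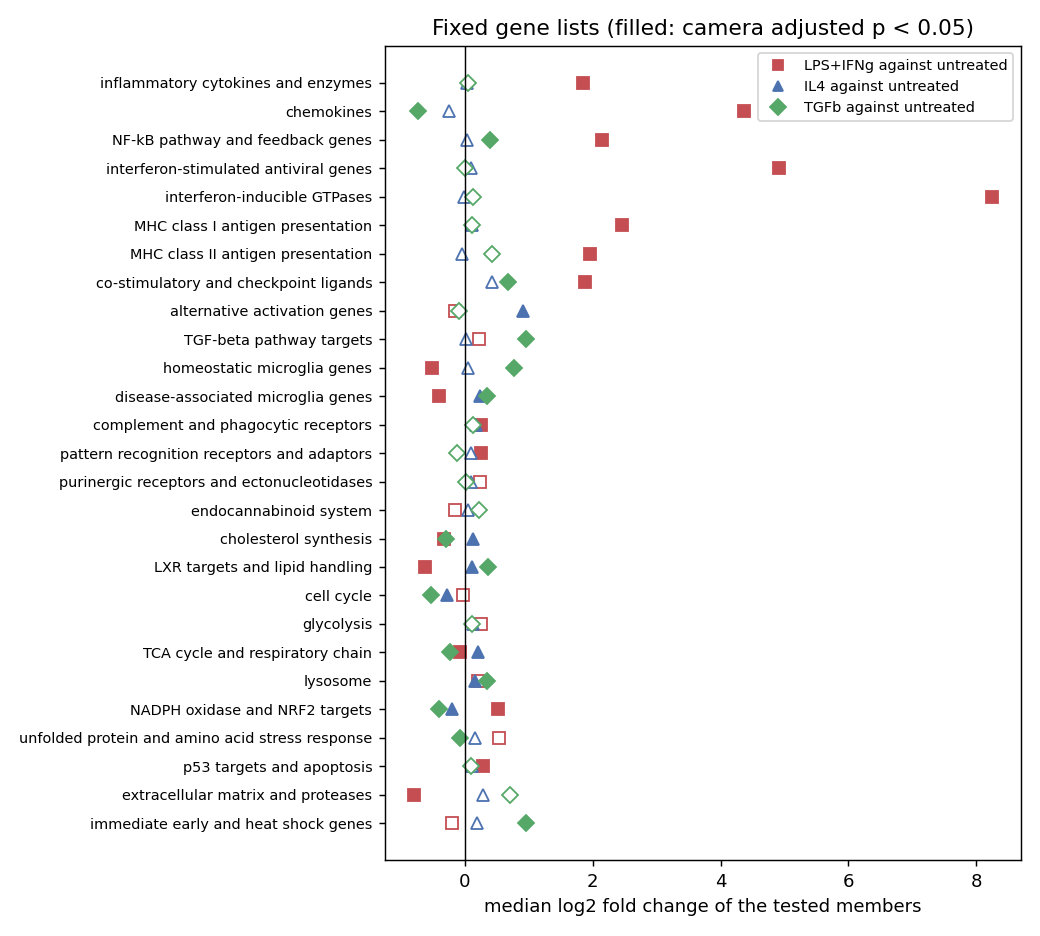
Median log2 fold change of the tested members of each of the 27 fixed gene lists with at least 5 members, for each stimulus against untreated; the symbol gives the stimulus, and filled symbols mark lists that camera called. The interferon-inducible GTPases have the highest median, 8.24 with LPS+IFNg, and the cell cycle list stands at -0.53 with TGFb and -0.28 with IL4.

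Few markers of other cell types could be tested, and those absent from the table used here were not analysed. Their small number therefore does not show that other cells were absent. Of the 9 lists of such markers, those of fibroblasts and of lymphocytes and erythroid cells had 0 tested genes and the others had 1 to 4 each, too few for a test of the list. Those that limma called are given on the log2 scale. With LPS+IFNg the monocyte gene Ly6c1 rose by 5.44 (SE 0.57), the astrocyte gene Aldh1l1 by 1.07 (SE 0.21) and the granulocyte gene S100a8 by 1.14 (SE 0.32). The neuron gene Syn1 fell by 1.86 (SE 0.13), the endothelial genes Vwf and Eng fell by 0.93 each (SE 0.1 and 0.27), the dendritic cell gene Itgax fell by 0.35 (SE 0.06) and the astrocyte gene Aldoc fell by 0.16 (SE 0.05). With IL4 Aldh1l1 rose by 0.75 (SE 0.21), the neuron gene Elavl4 by 0.68 (SE 0.19) and Aldoc by 0.2 (SE 0.05), while S100a8 fell by 1.68 (SE 0.32) and the stem cell gene Dnmt3l fell by 0.69 (SE 0.23). With TGFb the proteoglycan gene Cspg4 rose by 3.19 (SE 0.39), Vwf by 1.78 (SE 0.1), S100a8 by 1.48 (SE 0.32), Eng by 1.02 (SE 0.27), Itgax by 0.34 (SE 0.06) and Aldoc by 0.23 (SE 0.05), and Syn1 fell by 0.86 (SE 0.13). Cnp, Mbp, Egfl7, Slc1a2 and Zbtb46 were tested and were not called with any stimulus.

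LPS+IFNg was compared with IL4 to set the opposed activation states against each other. GTPase genes were again among the highest, with Gbp2 at 43190 ± 29000 (26450 without LPS+IFNg replicate 3) against 16.4 ± 2.98 and Tgtp2, which has a near-identical copy, at 2636 ± 283 against 1.41 ± 0.21. Serpina3f was among them too, with 21002 recovered reads with LPS+IFNg and 3 with IL4. Its depth-adjusted ratio was 8560 (95% counting interval 2930 to 41500), or 6420 (2510 to 23600) with the 4 reads that the floor allows at most with IL4. The genes furthest in the other direction were Ankrd37 (316 ± 41.3 with IL4 against 6.53 ± 1.08), the lipase gene Lipn (356 ± 26.9 against 7.71 ± 0.912), Cytip (1204 ± 106 against 33.4 ± 11.3), Tlr8 and Arg1. Arg1 had 288 recovered reads with IL4 and 1 with LPS+IFNg, a depth-adjusted ratio of 236 (95% counting interval 42 to 9340), or 78.5 (26.6 to 383) with the 3 reads that the floor allows at most with LPS+IFNg. In all 6422 genes differed, 3211 in each direction, and 1439 at least 2-fold. Of 22 alternative activation genes 14 were lower and 1 was higher with LPS+IFNg (14 and 2 adjusted over the list alone; camera adjusted p = 0.00023). Of 29 TCA cycle and respiratory chain genes 24 were lower and 0 higher (25 lower adjusted over the list alone; camera adjusted p = 3.06e-07, and adjusted p = 0.0515 with an estimated correlation).

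LPS+IFNg and TGFb were the furthest apart by the count of calls. Hspb7, a small heat shock protein gene, stood at 1041 ± 125 with TGFb and 7.25 ± 2.46 with LPS+IFNg, and Atp2b4 at 942 ± 16.4 against 6.98 ± 4.15, while Itgb5 and Cyp4f18 were 75.1-fold and 73.5-fold lower with LPS+IFNg. In the other direction Iigp1 had 24152 recovered reads with LPS+IFNg and 3 with TGFb, a depth-adjusted ratio of 8700 (95% counting interval 2980 to 42200), or 6520 (2550 to 23900) with the 4 reads that the floor allows at most with TGFb. In all 6975 genes differed, 3550 higher and 3425 lower with LPS+IFNg, and 1816 at least 2-fold. Of 19 homeostatic microglia genes 17 were lower and 0 higher with LPS+IFNg (18 lower adjusted over the list alone; median -1.46, camera adjusted p = 1.08e-08). Of 19 LXR targets 16 were lower and 1 was higher, the same adjusted over the list alone (camera adjusted p = 3.71e-07).

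IL4 and TGFb, both used to produce non-inflammatory states, differed in 4427 genes, 2309 higher and 2118 lower with IL4, and in 638 genes at least 2-fold. Gas7 (1208 ± 67.3 with IL4 against 8.01 ± 3.45), Cd74 (1525 ± 8.4 against 54.8 ± 7.28), the lectin gene Mgl2 (385 ± 7.69 against 21.5 ± 3.96) and the kallikrein gene Klk1b11 (80.8 ± 3.91 against 3.58 ± 2.48, or 2.17 without TGFb replicate 2), a member of a family of close copies, were highest with IL4. Arg1 was among them too, and it had 0 recovered reads with TGFb and was at least 84.8-fold higher with IL4 when TGFb is set at 3 counts. With the 2 reads that the floor allows at most with TGFb, the depth-adjusted ratio was 127 (95% counting interval 34.9 to 1060). Sgk1 (135 ± 19.3 with TGFb against 1.88 ± 0.845) and Skil (759 ± 12.1 against 25.5 ± 2.42) were among those highest with TGFb. All 29 TCA cycle and respiratory chain genes were higher with IL4 (median 0.44, camera adjusted p = 3.39e-15), as were 13 of 23 cholesterol synthesis genes, with 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 6.82e-06). Of 22 TGF-beta pathway targets 18 were lower and 0 higher with IL4, the same adjusted over the list alone (camera adjusted p = 1.3e-08). Camera called 17 of 27 lists between LPS+IFNg and IL4, 19 between LPS+IFNg and TGFb and 9 between IL4 and TGFb, of which 13, 9 and 6 held with an estimated correlation.

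**Figure D4:**
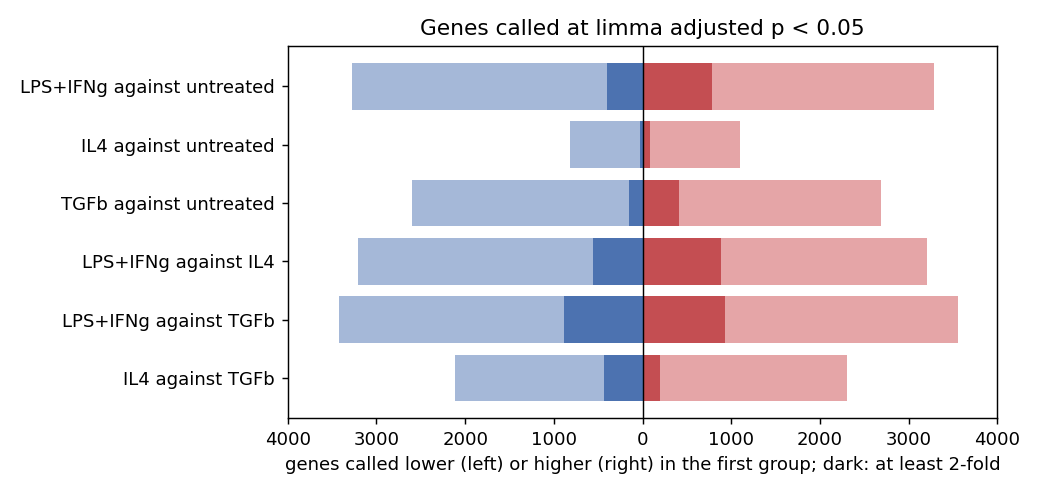
Number of genes called by limma in each of the 6 comparisons, higher in the first group to the right of 0 and lower to the left, with the dark part of each bar at least 2-fold. The longest bar to the right is 3550 genes, for LPS+IFNg against TGFb, and the shortest is 1101, for IL4 against untreated.

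A gene was taken as belonging to 1 state when it was called in the same direction against untreated cells and against both other stimuli. This held for 4244 genes with LPS+IFNg (2183 higher, 2061 lower), 2331 with TGFb (1188 higher, 1143 lower) and 626 with IL4 (442 higher, 184 lower), or 64.7%, 44.1% and 32.7% of the genes each stimulus changed against untreated cells.

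Calls against untreated cells were also compared between stimuli, which share the 6 untreated libraries. IL4 and TGFb shared 434 genes higher and 429 lower, where independent lists of those sizes would share 266 and 191 and simulated unchanged groups shared 0 and 0. The simulated groups held no changed gene, so their 0 shared calls cannot show how far shared controls add to the overlap of real calls. With the untreated libraries divided 3 and 3 between the stimuli, the shared calls averaged 295 higher and 263 lower over 20 arrangements, against 172 and 108 for independent lists of those sizes. The covariance of the fold changes was 0.0206 against 0.00993 in the simulation, a difference of 0.0106. With divided controls it was 0.0116. The simulated groups shared their controls, so the simulation is no reference for covariances with divided controls. LPS+IFNg and TGFb shared 837 genes higher and 919 lower, where independent lists would share 792 and 766, and with divided controls 668 and 737 against 623 and 599. Their covariance was 0.00692 against 0.00999 in the simulation, and -0.00199 with divided controls, so it did not exceed the value for unchanged groups. LPS+IFNg and IL4 shared 298 higher and 256 lower against 325 and 240, and with divided controls 209 and 140 against 224 and 142. Their covariance was -0.00138 against 0.00999, and -0.0103 with divided controls. Their opposite calls numbered 305 genes higher with LPS+IFNg and lower with IL4 and 478 the other way, against 241 and 324 for independent lists. For LPS+IFNg and TGFb, 761 were higher with LPS+IFNg and lower with TGFb and 852 the other way, against 768 and 791. For IL4 and TGFb, 234 were higher with IL4 and lower with TGFb and 170 the other way, against 257 and 197.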

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

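The tests of the response size in LPS+IFNg replicate 3 and of the recovered Gas7 reads were chosen after those results had been seen, and the fit without the 3 libraries with the fewest reads was added after the data had been seen.

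Untreated replicate 6 was set apart by its depth, at 18676181 recovered reads where the other 5 untreated libraries held 2682564 to 6822452 (gap over range 0.741, above the critical value of Dixon's test at 95%). Among the untreated values of 247 named genes, 14 had 1 library apart from the other 5, where chance alone gives about 12. These were Ciita (1) and Olfml3 (1), each with 1 library above the floor, and Ccnb1 (0.773), Fas (0.763), Idi1 (0.746), Mcm2 (0.726), Gas7 (0.687), Azin2 (0.681), Marco (0.67), Clec4e (0.659), Gas6 (0.649), Cst7 (0.644), Atp2b4 (0.632) and Havcr2 (0.632). Replicate 4, the shallowest library, was the one apart for 5 of the 14 genes.

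LPS+IFNg replicate 3 stood apart from replicates 1 and 2. Depth was argued against, since with the 3 libraries thinned to the same number of reads the median chi-square per gene of pairs with replicate 3 was still at least 4.29 times that of the pair without it. GC content and transcript length took 1.63% of the variance of its difference from the others. Of 1073 genes called and at least 2-fold changed without it, 60.9% lay further from untreated in replicate 3, which was 65.3% of the genes that were higher and 52.2% of those that were lower. A stronger response to the same stimulus may therefore account for part of the difference, but 60.9% lay between the bounds set for and against it, and a difference in culture or handling was not tested.

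Gas7 was nearly absent in all 3 TGFb libraries, with 34 recovered reads in total against 6830 in the untreated libraries, while its normalized value was 1131 to 1258 in the IL4 libraries and 1400 to 1583 in the LPS+IFNg libraries. The floor was argued against, since the 3 TGFb values, 4.268 to 11.06, lay above it. The deposited scaling was argued against, since the depth-adjusted ratio of recovered reads was 0.00755 with an upper 95% counting limit of 0.0106. That ratio rests on the same values scaled by library totals, so it is not separate evidence of the low level. Loss of a chromosome region that reached the 8 tested genes within 1 Mb was argued against by their values. Their median log2 fold change was 0.24 (SE 0.192, from the spread between the genes and not between libraries) and their lowest was -0.51. The nearest on either side were Myh3, which ends at 67102291, and Stx8, which starts at 67966193. No tested gene but Gas7 lies between them, so a loss within that stretch was not covered. For assignment of its reads to a neighbour, the largest gain, at Pik3r5 (1581 to 1975), was 34.1% of the Gas7 loss, between the bounds set beforehand. No tested neighbour gained enough to hold most of the lost reads, which argues against this account for most of the loss. Pik3r5 starts at 68432121, and Stx8 and Ntn1 lie between it and Gas7. A smaller part of the loss stays open. Repression by TGFb may explain the change and was not tested. A lesion confined to Gas7 or to the stretch between Myh3 and Stx8 was not tested either, nor was a change made to the Gas7 values before deposit. The 145-fold lower level would need a messenger half-life of at most 3.3 h if transcription stopped at once.

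Cell cycle genes were lower with TGFb, with a median log2 fold change of -0.53 over 35 genes. The authors' scaling was argued against, since under total, median-of-ratios and quantile scaling the median nearest 0 was -0.53 (SE 0.0506). After each library's trend with GC content and transcript length was removed it was -0.54 (SE 0.0519), and without the 3 libraries with the fewest reads it was -0.54 (SE 0.0524), so these did not account for it either. Each SE of a median here comes from the spread between the 35 genes, taken as independent, and does not measure the spread between libraries. That fewer cells were dividing may explain the pattern, a hypothesis that was not tested.

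Other divisions of the libraries were counted for each comparison. Each fit for a comparison used the libraries of its 2 groups alone, so its counts can differ from those of the fit over all 15 libraries. Among the 84 divisions of the 9 libraries of each stimulus and the untreated group, 1 gave as many genes as the real one, the real one itself. The real counts were 6212 for LPS+IFNg (highest other 0), 2419 for IL4 (highest other 1) and 5746 for TGFb (highest other 0). A share of 1 in 84 lies under the limit of 0.05, so a random division was argued against. Every other division mixed libraries of the 2 groups, so the counts cannot tell the stimulus from another difference between the groups. For the number of lists called by camera at its preset correlation, 1 of 84 was as large for LPS+IFNg (18 lists, highest other 15), 2 of 84 for IL4 (10, highest other 10) and 1 of 84 for TGFb (12, highest other 11). These shares lay under the limit of 0.05, but arbitrary divisions also called many lists, and for IL4 another division called as many as the real one. The list counts alone therefore say little. Between stimuli 3 against 3 libraries make 10 divisions, too few for a share under 0.05. For LPS+IFNg against IL4, LPS+IFNg against TGFb and IL4 against TGFb the real divisions gave 5580, 6372 and 5018 genes, where 1 of 10 was as large and the highest other was 0 in each. They gave 17, 17 and 10 lists, where 1, 2 and 1 of 10 were as large and the highest others were 15, 17 and 5. For genes of 1 state, 100 groupings of the 15 libraries were counted, made up of the real one and random ones with the same group sizes. For LPS+IFNg 1 was as large, the real one itself (4244 genes, highest other 0). For TGFb 1 was as large, again the real one (2331, highest other 49). For IL4 2 were as large, the real one (626) and a random one (1194) that put the IL4 name on the 3 TGFb libraries.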

How the results depend on the processing

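The fits with edgeR, with DESeq2, without the 3 libraries with the fewest reads and with floored values at their highest reads were chosen after seeing the data. With edgeR 6701, 2067 and 5281 genes were called for LPS+IFNg, IL4 and TGFb against untreated, with DESeq2 6419, 1957 and 5075, and without the 3 shallow libraries 6464, 1655 and 4214. Of 354 named results, 341 kept their direction and side of the threshold under every alternative run, and 0 of the others changed direction. The count of called genes moved by over 1.5 times for IL4, to 1090 at an adjusted p under 0.01 and between 1139 and 2716 with 1 library left out, lowest without IL4 replicate 2 and highest without LPS+IFNg replicate 3. The 2-fold count was 64 for IL4 with a pseudocount of 10 and 372 for TGFb with a minimum of 50, where fewer genes were tested. Genes of 1 state for IL4 numbered 979 with library weights and 369 at an adjusted p under 0.01. With an estimated correlation 10, 3, 3 and 9 lists were called for LPS+IFNg, IL4 and TGFb against untreated and LPS+IFNg against TGFb, and fry called 16 for IL4 and 16 for IL4 against TGFb. Shared calls of LPS+IFNg with IL4 numbered 182 higher and 596 lower under total scaling, 425 lower under quantile normalization, 457 and 399 with library weights, and 167 and 105 at an adjusted p under 0.01. Those of LPS+IFNg with TGFb numbered 555 and 1558 under total scaling, and 556 higher at an adjusted p under 0.01. Those of IL4 with TGFb numbered 262 and 834 under total scaling, 700 and 655 with library weights, and 246 and 207 at an adjusted p under 0.01. With 1 library left out they ranged from 274 to 665 higher and from 223 to 625 lower for IL4 with TGFb, and from 192 to 396 higher and 126 to 378 lower for LPS+IFNg with IL4, each lowest without IL4 replicate 2 and highest without LPS+IFNg replicate 3. Leaving out LPS+IFNg replicate 3 did not alter the IL4 and untreated values. The rise of the IL4 count to 2716 therefore came through the estimate of spread that the groups share. A fit of the IL4 and untreated libraries alone called 2419 genes. Total scaling put the median log2 fold change of all genes at -0.12, -0.064 and -0.062 for LPS+IFNg, IL4 and TGFb against untreated. Apart from that rise, the stricter threshold and the higher minimum, the cause was not tested. No paired analysis was possible because the labels give no replicate numbers shared between groups.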

Other observations

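No test reported in this part was chosen after its result had been seen. Several fixed lists not described above were called by camera with LPS+IFNg. Of 13 extracellular matrix and protease genes 8 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.0405 with an estimated correlation). The macrophage elastase gene Mmp12 went from 87.2 ± 6.17 to 9.23 ± 0.758 and the protease inhibitor gene Timp2 from 1121 ± 45.9 to 463 ± 53.2 (SD, n = 6 and 3). Of 18 p53 target and apoptosis genes 10 rose and 3 fell (10 and 4 adjusted over the list alone). Mdm2, which encodes the ubiquitin ligase of p53, went from 781 ± 32.4 to 1835 ± 190 and the stress gene Sesn1 from 425 ± 25.4 to 105 ± 7.33. The camera adjusted p was 0.0355, with an adjusted p = 0.44 with an estimated correlation and an adjusted p = 0.112 without replicate 3 of the LPS+IFNg group. The death receptor gene Fas had 3 recovered reads in untreated cells and 518 with LPS+IFNg, a depth-adjusted ratio of 283 (95% counting interval 96.2 to 1380), or 170 (72.2 to 525) with the 5 untreated reads that the floor allows at most. Its mean with LPS+IFNg was 167, and 109 without replicate 3. Of 29 TCA cycle and respiratory chain genes 13 fell and 4 rose, the same adjusted over the list alone, such as the isocitrate dehydrogenase gene Idh3a (1809 ± 70.4 to 1210 ± 38.3). That list had a camera adjusted p of 0.011 and an adjusted p = 0.315 with an estimated correlation.

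With IL4, 6 of 20 glycolysis genes rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0359, and adjusted p = 0.569 with an estimated correlation), led by Pfkfb4 (130 ± 7.08 to 198 ± 24.6). That call was also lost under quantile normalization (adjusted p = 0.726) and total scaling (adjusted p = 0.0679). It was lost without IL4 replicate 1 (adjusted p = 0.0797) and without untreated replicate 3 or 6 (adjusted p = 0.0619 and 0.0517) too. Of 23 cholesterol synthesis genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), for example Nsdhl (632 ± 28.6 to 825 ± 28.6). The list had a camera adjusted p of 0.00275 and an adjusted p = 0.103 with an estimated correlation. With TGFb, 11 of 20 genes of the NF-kB pathway rose and 2 fell (12 and 2 adjusted over the list alone). They included the inhibitor gene Nfkbie (97.1 ± 9.46 to 206 ± 19.2) and, lower, Tnip3 (240 ± 23.3 to 114 ± 13.7). Its camera adjusted p was 0.0223, with an adjusted p = 0.35 with an estimated correlation.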
